A study of Escherichia coli str. K-12 substr. MG1655 with 36 samples.

How the data were processed

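Total mRNA and ribosome footprints were measured in 18 cultures of Escherichia coli K-12 MG1655 grown in defined rich medium at 30 °C. In the heat experiment, without plasmid, cells stayed at 30 °C or were moved to 42 °C for 10 or 20 min (3 cultures each). In the plasmid experiment, at 30 °C with 0.2% arabinose, cells carried the empty pBAD vector (4 cultures) or pBAD with wild-type σ32 (3) or σ32 I54N (2). Per the labels' protocols, cells were broken in liquid nitrogen. Total RNA was extracted, fragmented by alkali and size-selected at 20 to 40 nt, while footprints came from polysomes digested with MNase and monosomes purified on sucrose gradients. Samples were assigned to groups, replicates and library kinds from their titles.

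Both processed tables that the authors deposited were used. The deposited raw table holds estimated counts of reads per gene (expected counts, not normalized), since 40.8 to 87.5% of values in a library are whole numbers (to within 0.001) and the rest are fractions. The deposited normalized table holds RPKM values by the authors. In its mRNA columns 98.1 to 99.3% of genes follow the raw count divided by gene length and a constant to within 1%, and its footprint columns carry a further factor that differs with gene length (ratio of genes over 1500 bp to genes under 450 bp 1.01 to 1.46), whose source is not given in the sources used here. The authors' processing notes name CASAVA, Bowtie and edgeR without versions, and the genome build and annotation are not stated, so no positions are given. Gene order, used in the neighbour test alone, came from a RefSeq table of MG1655 genes that holds no strand, so the genes on both sides were taken.

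Of 4497 entries in the raw table, 4192 coding genes that also stand in the normalized table were analysed, after adding up 8 pairs of gene copies that the authors had merged. The 297 other entries, among them 22 ribosomal and 86 transfer RNA genes, were left out of the main counts. Estimated counts were rounded to whole numbers. Coding reads per library have a median of 1259638 for mRNA and 3769926.5 for footprints. The lowest ratio of observed to Poisson variance between replicates, averaged over genes with at least 20 reads in the pair, is 2.05, between the I54N mRNA libraries. The I54N footprint libraries stand at 5.97, and the lowest other footprint pair at 13.06.

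Changes were tested per gene with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with its defaults, quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05), separately for the heat and plasmid experiments and for mRNA and footprints, with all 3 groups of an experiment in the fit. Translation efficiency was tested as the difference between the footprint and mRNA changes in a joint fit of both kinds, and heat was set against σ32 as a difference of changes in a joint fit of both experiments. Standard errors are on the log2 scale from the same fits. CPM values use TMM library sizes, computed over all libraries of one kind where rpoH is described. Shares of coding reads were compared by exact two-sided permutation tests, and within same-numbered pairs by an exact paired test. In all, 31 lists of genes of known function were written from general knowledge before the data were examined, and tested as sets with camera (limma 3.58.1) at its preset correlation of 0.01 and with the correlation estimated from the data. Counts of list members that rose or fell are those past the threshold over all genes, and the counts adjusted over the list alone are given beside them.

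Genes are named by a fixed rule: rpoH and the chaperones always; in heat and plasmid comparisons the 10 largest rises and falls in mRNA, and 5 in translation efficiency, among genes past the threshold with an average log2 CPM of at least 5 and no overlap between replicates; in the other contrasts the 5 largest each way; and up to 4 members of a list with the largest changes. Not every gene allowed by the rule is named. Footprint values are given for genes the rule names in mRNA.

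Recovery was tested on simulated data, with known changes written into counts drawn from the fitted means of the control group: at 2-fold and 4-fold, 34.3 and 92.4% of mRNA changes were recovered for 20 min of heat, 50.7 and 95.5% for wild-type σ32 and 52.2 and 90.9% for I54N. For translation efficiency 0 and 22.7% were recovered at 20 min, 31.3 and 66.7% with wild-type σ32 and 7.5 and 57.6% with I54N, and for footprints at 10 min 0 and 13.6%. The draws treat the mRNA and footprints of a culture as independent. Their spread is that of the main fit, which in heat includes the 20 min footprint library of replicate 2.

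Whether replicate numbers pair cultures across groups was checked by correlating residuals of same-numbered libraries. They pair for heat mRNA (r 0.38 to 0.78), for footprints at 30 °C and 10 min (0.52 to 0.77) and for vector and wild-type σ32 (mRNA 0.26 to 0.61, footprints 0.54 to 0.79), but not for footprints at 20 min (down to −0.37) or for I54N (−0.06 to 0.03). A fit with the replicate number as a block is therefore given beside the results where the numbers pair. For translation efficiency the block is the culture instead, which pairs the mRNA and footprints of 1 culture. Residuals of mRNA and footprints of a culture correlate above 0.1 in 16 of 18 cultures. They stand at −0.05 in both I54N cultures, so variation of its own was not seen for an I54N culture.

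The alternatives tried were RLE size factors, library totals alone, no filter on low counts, a mean count of at least 64, DESeq2 1.42.0, the replicate block, only the groups compared in the fit, limma on the authors' normalized values (pseudocounts 1 and 0.1), limma on the log2 ratio per culture, and each library left out in turn. Chosen after seeing the data were all entries of the raw table, the library batch as a term, the 20 min footprint library of replicate 2 left out of the fit, shares within same-numbered pairs, and the authors' values for translation efficiency. Tables were prepared with Python 3.11.15 and figures drawn with matplotlib 3.10.9.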

Results

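Escherichia coli K-12 MG1655 was followed through a shift from 30 °C to 42 °C and, in a separate experiment at 30 °C, with the heat shock sigma factor σ32 made from a plasmid. Each of 18 cultures gave 1 library of fragmented total mRNA and 1 library of ribosome footprints. Coding reads ranged from 317046 to 3159951 in the mRNA libraries and from 744046 to 10424079 in the footprint libraries, and ribosomal RNA took 50.5 to 92.2% of the mRNA reads and 22.6 to 78.6% of the footprint reads. The mRNA libraries of vector replicate 4 and of both I54N cultures carry 30.6 to 34.9% transfer RNA against at most 3.81% elsewhere. The labels name no library batches, and these 3 are treated as one batch inferred from that share, which is assumed for their footprint libraries too. The footprint libraries of the 3 cultures do not stand apart in transfer RNA (8.42, 10.0 and 17.7% against 7.60 to 39.8% in the other plasmid footprint libraries). The labels do not say that the cultures of a group were grown independently, so the p-values measure the spread between samples, which may be partly technical. For I54N (n = 2) the mRNA and footprint residuals of a culture do not correlate (r = −0.05). Variation between its cultures was thus not seen, and its spread may be technical alone.

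The plasmids raised rpoH, the gene of σ32, above every vector library. In the mRNA libraries rpoH stood at 371 ± 19.5 CPM (mean ± SD, n = 4) with the empty vector, at 1357 ± 454 CPM with wild-type σ32 (n = 3) and at 1184 ± 122 CPM with σ32 I54N (n = 2). I54N is a form of the factor that the cell holds in check less tightly. In log2 units rpoH mRNA rose by 1.84 ± 0.18 (SE) with the wild type (adjusted p = 0.00154, edgeR's quasi-likelihood test with Benjamini-Hochberg) and by 1.69 ± 0.20 with I54N (adjusted p = 0.000216). Footprints on rpoH rose by 2.50 ± 0.25 and 2.25 ± 0.27 (adjusted p = 0.00563 and 0.000843 in the same edgeR test). Without vector replicate 2 or 4 the wild-type footprint call is lost (0 genes instead of 1). With the library batch as a term the I54N footprint value is 2.44 with an edgeR adjusted p = 0.0502. On the TMM scale heat moved rpoH little. Its mRNA went from 386 ± 29.2 CPM at 30 °C to 479 ± 48.1 CPM after 10 min and 457 ± 56.8 CPM after 20 min (n = 3 each), a change of 0.36 ± 0.16 at 10 min (edgeR adjusted p = 0.14, and 0.0387 with the replicate number as a block). Its footprints stood at 342 ± 51.3, 384 ± 8.41 and 309 ± 98.7 CPM, so on this scale they moved less than replicates spread. The low 20 min mean comes from replicate 2 at 195.7 CPM, a library that departs from its group, against 373.6 and 358.9 CPM in replicates 1 and 3. Without TMM, as a part of all coding reads, rpoH was higher at 10 min. Each 10 min library stood above each 30 °C library of its kind.

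Within 10 min at 42 °C mRNAs of most chaperones, the proteins that hold and refold others, rose. Of 11 chaperone genes 7 rose: clpB, which pulls proteins out of aggregates, by 2.16 ± 0.34 log2, groL by 1.98 ± 0.23 and groS by 1.77 ± 0.27 (the folding chamber), htpG (Hsp90) by 1.97 ± 0.28, ibpB (a small heat shock protein) by 1.46 ± 0.35, dnaK (Hsp70) by 1.37 ± 0.24 and its exchange factor grpE by 0.75 ± 0.17 (n = 3 against 3). The other 4 did not pass the test: dnaJ changed by 0.33, hslO by −0.06, hslR (a ribosome rescue gene, counted among the 11 throughout) by −0.33 and ibpA by −0.47. Of these dnaJ passed with the replicate number as a block (edgeR adjusted p = 0.0329). The ibpB call is lost without heat10 replicate 2 (1.25) or heat0 replicate 3 (1.47), and the grpE call without heat10 replicate 1 (0.60), heat0 replicate 2 (0.67) or heat0 replicate 3 (0.73). Of 10 heat shock proteases only hslU (0.83 ± 0.21) and lon (0.55 ± 0.15) rose, 3 adjusted over the list alone and 4 with the block. No protease passed without heat0 replicate 2, heat0 replicate 3, heat10 replicate 1 or heat10 replicate 2 (hslU 0.67 to 0.80, lon 0.44 to 0.57), and 4 did without heat10 replicate 3. Of 31 further σ32 genes 3 rose and 2 fell, but with library totals as the only scaling 11 rose and 0 fell. The 2 falls are 0 without heat10 replicate 1 or heat0 replicate 3 and 1 without heat10 replicate 2 or 3. Among the risen are ldhA (1.50 ± 0.41) and ycjF (1.00 ± 0.18), where ldhA does not pass without heat10 replicate 1 (1.05), heat0 replicate 2 (1.27) or heat0 replicate 3 (1.35).

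Genes of the general stress response, run by the sigma factor RpoS, rose at 10 min. Of 28 such genes 18 rose (23 adjusted over the list alone) and 0 fell, including wrbA (a quinone reductase) by 2.84 ± 0.65, poxB (pyruvate oxidase) by 2.80 ± 0.33, tktB (transketolase) by 2.72 ± 0.20 and otsB (trehalose synthesis) by 2.65 ± 0.43. The largest rises among well-expressed genes were hchA (a protein repair enzyme) by 4.82 ± 0.57, ycaC by 3.82 ± 0.43, hdhA by 3.63 ± 0.38 and appY by 3.55 ± 0.65, none of them on that list. The wrbA call is lost without heat0 replicate 2 (2.66). Genes that park ribosomes rose too, 4 of 7, with ygaM at 3.00 ± 0.29, rmf at 2.15 ± 0.27 and elaB at 1.85 ± 0.20. Of these elaB is also on the general stress list.

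Iron uptake, flagellar, ribosomal protein and cold shock genes fell in mRNA in the same 10 min. Of 28 iron uptake genes 21 fell (24 adjusted over the list alone), with entC (enterobactin synthesis) at −4.71 ± 0.53 and the receptors fiu at −3.90 ± 0.38 and cirA at −3.49 ± 0.42. Of 45 flagellar and chemotaxis genes 35 fell (41 adjusted over the list alone; 24 with library totals alone), with the hook-length gene fliK at −2.17 ± 0.35 and the rod gene flgG at −2.15 ± 0.27. Of 54 ribosomal protein genes 41 fell (median −0.85), with rpmJ at −1.10 ± 0.21 and rplI at −1.05 ± 0.27. That count is 45 adjusted over the list alone, 26 without heat0 replicate 3, 23 with library totals alone and 54 with the block. The rplI call is lost without heat10 replicate 1 (−1.07), heat10 replicate 3 (−0.93), heat0 replicate 2 (−0.94) or heat0 replicate 3 (−1.12). Of 11 cold shock genes 8 fell (10 adjusted over the list alone, where 1 also rose), among them cspE at −2.42 ± 0.27, deaD (an RNA helicase) at −1.69 ± 0.44, cspC at −1.66 ± 0.17 and cspA at −1.50 ± 0.26. The count is 4 without heat10 replicate 1 or heat0 replicate 3, and with library totals alone 5 fell and 1 rose. Of 31 genes of respiration and ATP synthase 20 fell (24 adjusted over the list alone; 11 with library totals alone), such as sdhC at −1.49 ± 0.40, while the oxygen-scavenging oxidase genes cydA (1.50 ± 0.35) and cydB (1.63 ± 0.42) rose. Those 2 rises are 0 without heat0 replicate 2 or 3 and 1 without heat10 replicate 2. The calls of deaD (−1.79 to −1.37) and sdhC (−1.63 to −1.16) are lost without heat10 replicate 1, heat10 replicate 2, heat0 replicate 2 or heat0 replicate 3. Of 26 purine and pyrimidine genes 12 fell (15 adjusted over the list alone), a count of 23 with the block, of 1 with library totals alone and of 2 without heat0 replicate 3. It is 3 without heat0 replicate 2 and 4 without heat10 replicate 1, 2 or 3. Asparagine synthetase, asnA, fell by 3.06 ± 0.24.

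Over all 3450 genes tested, 670 passed an adjusted p of 0.05 at 10 min in edgeR's quasi-likelihood test (337 higher, 333 lower; 404 of them by at least 2-fold). With the replicate number as a block the count is 1485 (711 higher, 774 lower). It is 345 without heat0 replicate 3, 416 without heat0 replicate 2 and 432 without heat10 replicate 1. Under library totals alone it is 1015 (857 higher, 158 lower), because that scaling moves the median of all genes from 0.05 to 0.43 log2. All changes are relative to other mRNAs, and amounts per cell were not measured. Camera called 15 of 31 lists with its preset correlation and 2, iron uptake and flagella (adjusted p = 0.045 each), with an estimated correlation. At 3 libraries a group, 31.3% of simulated 2-fold changes and 77.3% of 4-fold changes were recovered, so genes left uncalled here are often undecided.

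**Figure D1:**
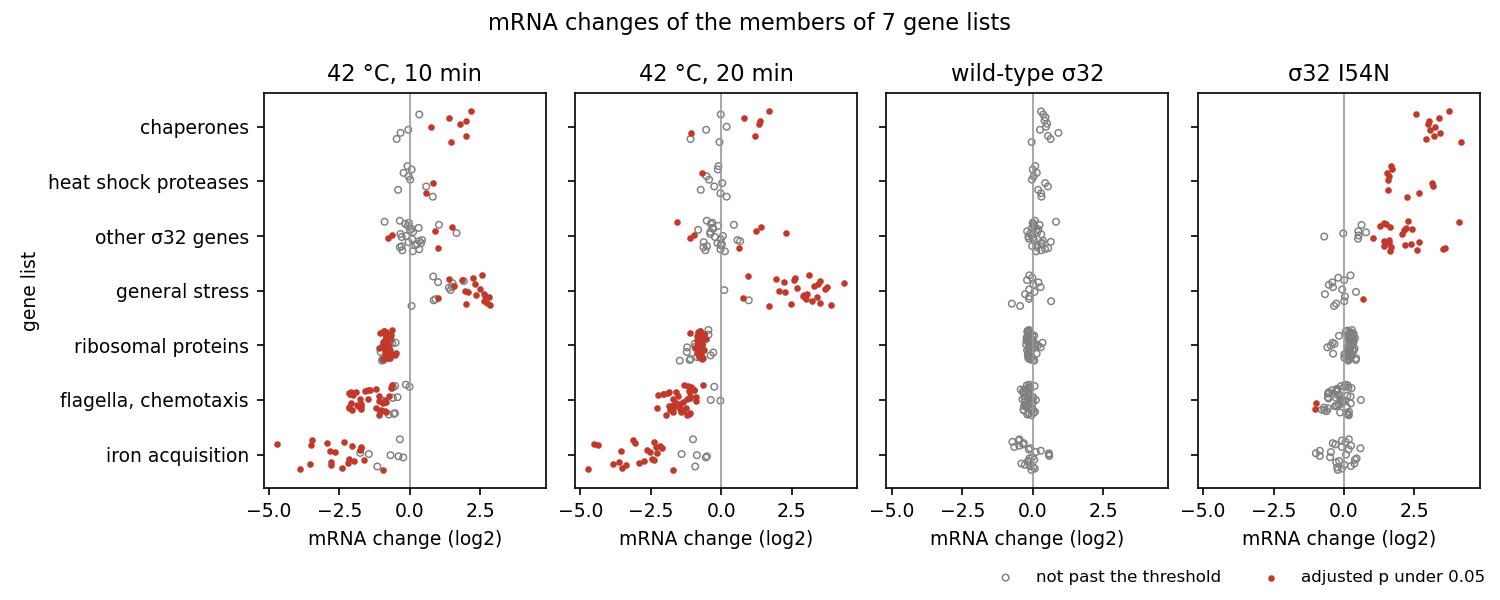
Log2 change in mRNA (horizontal axis) of each tested member of 7 gene lists (lines of points) in 4 comparisons, with filled points for genes past an edgeR adjusted p of 0.05. Of 11 chaperones 7 rose after 10 min at 42 °C, 0 with wild-type σ32 and 11 with σ32 I54N, and the ribosomal protein falls at 10 min shrink from a median of −0.85 to −0.47 under library totals alone.

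After 20 min more general stress genes and fewer chaperones stood above their 30 °C level than after 10 min. Of 28 general stress genes 26 rose (27 adjusted over the list alone), among them gadE (acid resistance) by 4.36 ± 0.81 and katE (catalase) by 3.69 ± 0.35, and hchA reached 5.58 ± 0.58 (n = 3 against 3). Of 11 chaperones 5 rose (clpB 1.68 ± 0.33, groL 1.37 ± 0.23, groS 1.33 ± 0.27, htpG 1.18 ± 0.27 and dnaK 0.82 ± 0.24), and hslR (ribosome rescue) fell by 1.06 ± 0.17. The fallen chaperones are 2 adjusted over the list alone and 3 with the replicate number as a block, where ibpA (−1.09 ± 0.39) and hslO (−0.54 ± 0.24) pass, and 2 without heat20 replicate 2, where hslO (−0.82) passes. The 5 rises are 3 without heat0 replicate 3, where htpG (1.06) and dnaK (0.71) do not pass. The dnaK call is also lost without heat20 replicate 1 (0.68), heat20 replicate 3 (0.80) or heat0 replicate 2 (0.74). Of 10 heat shock proteases only ftsH changed, by −0.70 ± 0.19, a call lost under library totals alone and without heat0 replicate 2 or 3 or heat20 replicate 1 or 3 (−0.73 to −0.59). The fallen proteases are 2 without heat0 replicate 1 and 4 with the block or without heat20 replicate 2. Of the 31 further σ32 genes 4 rose and 3 fell, 6 and 12 with the block. The 4 rises are 1 without heat20 replicate 3 and 2 without heat20 replicate 1 or heat0 replicate 2 or 3.

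Iron uptake lost 22 of 28 genes at 20 min (24 adjusted over the list alone), led by fiu at −4.74 ± 0.39 and entC at −4.52 ± 0.51. Flagella lost 42 of 45, with fliK at −2.29 ± 0.35 and the rod gene flgJ at −2.26 ± 0.23. Of 54 ribosomal protein genes 38 fell, a count of 52 adjusted over the list alone, 23 without heat0 replicate 3 and 14 with library totals alone. Of 11 cold shock genes 9 fell and 1 rose (0 without heat20 replicate 1 or 3 or heat0 replicate 2), with cspF at −2.60 ± 0.44 and cspA at −1.75 ± 0.26. Of 7 ribosome-parking genes 5 rose (6 adjusted over the list alone), with rmf at 3.02 ± 0.27 and raiA at 2.02 ± 0.63. The raiA call is lost without heat20 replicate 1 (1.34), heat20 replicate 3 (2.16), heat0 replicate 2 (1.77) or heat0 replicate 3 (1.89). Of 31 genes of respiration and ATP synthase 16 fell and 1 rose, where the rise is 0 without heat20 replicate 1 or 2 or heat0 replicate 2 or 3 and 2 without heat20 replicate 3. Of 26 purine and pyrimidine genes 5 fell, 3 adjusted over the list alone, 15 with the block and 1 with library totals alone. That count is 1 without heat20 replicate 1 or heat0 replicate 2 or 3, 2 without heat20 replicate 3 and 11 without heat20 replicate 2. In all, 953 of 3450 genes passed the edgeR test (498 higher, 455 lower) and 1821 with the block. The count is 548 without heat0 replicate 3, 600 without heat20 replicate 1, 606 without heat0 replicate 2 and 1213 (996 higher, 217 lower) with library totals alone, where the median of all genes sits at 0.39 log2. Camera called 15 of 31 lists, and 2 (iron uptake and flagella, adjusted p = 0.045 each) with an estimated correlation.

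Between 10 and 20 min few mRNAs can be told apart. The cytochrome bd-II oxidase gene appC rose by 2.13 ± 0.26, while proW (glycine betaine uptake, −1.62 ± 0.25), metE (methionine synthase, −1.24 ± 0.18), phoU (−1.15 ± 0.18) and pstB (−1.08 ± 0.16), both of phosphate uptake, fell (n = 3 against 3). None of the 5 calls outlasts the loss of any 1 library, where the count is 0. Chaperone changes from 10 to 20 min are negative in value, ibpB at −1.52 ± 0.35, htpG at −0.80 ± 0.27 and groL at −0.61 ± 0.23, and pass only with the replicate number as a block (edgeR adjusted p = 0.00177, 0.00479 and 0.00542). With the block 6 of 11 chaperones and 5 of 10 proteases fell and 14 of 28 general stress genes rose, against 5, 3 and 11 adjusted over the list alone and 0 in each over all genes. In edgeR 5 genes of 3450 pass (286 do at unadjusted p < 0.05), 223 with the block and 30 by DESeq2. Camera called 15 of 31 lists for mRNA and 14 for footprints, and 0 each with an estimated correlation. For footprints the count is 0 in edgeR (206 at unadjusted p < 0.05), 7 by DESeq2 and 2 with the block, although footprint replicates at 20 min do not pair by number.

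Footprints followed the same groups of genes in heat with less certainty. After 10 min hchA rose by 4.25 ± 0.86 and ibpB by 2.09 ± 0.46, and fiu fell by 4.69 ± 0.98 (edgeR adjusted p = 0.0406, 0.0474 and 0.0408; n = 3 against 3). The chaperones clpB (2.56 ± 0.64), htpG (2.12 ± 0.57) and groL (2.01 ± 0.57) show values near those of their mRNA without passing. Of these clpB and htpG pass with the replicate number as a block (edgeR adjusted p = 0.0125 and 0.0328). So does ibpA at −1.46 ± 0.47 (0.0303), a lower value than that of its mRNA. Of the 28 general stress genes 7 rose, of 28 iron uptake genes 6 fell and of 45 flagellar genes 8 fell. These counts are 19, 20 and 23 adjusted over each list alone, 16, 16 and 19 with the block, and 13, 1 and 1 with library totals alone. By edgeR 64 genes of 3341 passed (40 higher, 24 lower; 535 at unadjusted p < 0.05). The count is 289 with the block, 226 by DESeq2, 94 (87 higher, 7 lower) with library totals alone and 307 when the 20 min footprint library of replicate 2 is left out of the fit. Every one of these list counts becomes 0, and the count over all genes 0 or 1, without any 1 of the 6 libraries compared. The 3 named calls are lost with them, at 3.45 to 4.94 for hchA, 1.97 to 2.24 for ibpB and −4.94 to −4.40 for fiu.

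At 20 min footprints rose on 23 of 28 general stress genes (27 adjusted over the list alone), with hchA at 5.14 ± 0.89, and fell on fiu (−4.13 ± 0.95), cspA (−2.70 ± 0.57) and ibpA (−2.01 ± 0.48; n = 3 against 3). Of 28 iron uptake genes 9 fell, of 45 flagellar genes 14 and of 13 cold shock genes 6, with 17, 25 and 10 adjusted over each list alone, and 2, 5 and 3 under library totals alone. Replicate 2 of this group departs from the other 2 libraries. Without heat20 replicate 2 the 3 counts are 21, 31 and 7 and 4 chaperones rise. Iron uptake has 2 falls without heat0 replicate 2 or heat20 replicate 1, 3 without heat0 replicate 1 or 3 and 5 without heat20 replicate 3. Flagella have 0 falls without heat0 replicate 2, 2 and 3 without heat0 replicates 1 and 3, and 5 and 7 without heat20 replicates 1 and 3. Cold shock genes have 0 without heat0 replicate 1 or 2, 1 without heat0 replicate 3 and 2 without heat20 replicate 1. The calls of fiu (−4.35 to −3.49) and cspA (−2.87 to −2.66) are lost without heat20 replicate 1 or any 1 heat0 replicate, that of hchA without heat0 replicate 1 (4.88) or 2 (4.77), and that of ibpA (−2.15 to −1.89) without any library but heat20 replicate 2. The edgeR count over 3341 genes goes from 343 (238 higher, 105 lower) to 754. Without heat0 replicate 2 the count is 5, with 0 general stress genes. It is 36 without heat0 replicate 1, 40 without heat0 replicate 3 and 72 without heat20 replicate 1, where the general stress genes number 5, 6 and 11. With library totals alone it is 410 (371 higher, 39 lower), where the median of all genes moves from 0.13 to 0.72, and by DESeq2 it is 597. Camera called 15 lists at 10 min and 16 at 20 min, and only flagella (adjusted p = 0.00552 and 0.0152) with an estimated correlation.

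Translation efficiency, the change in footprints beyond the change in mRNA, could not be told from no change for any gene in heat. At 10 min the values are −0.12 ± 0.34 log2 for rpoH, 0.52 ± 0.75 for clpB, 0.73 ± 0.55 for ibpB, −0.86 ± 0.63 for ibpA, 0.03 ± 0.66 for dnaK and 0.13 ± 0.62 for groL (n = 3 against 3), and at 20 min 1.14 ± 0.43 for hslR and 1.33 ± 0.57 for ibpB. By edgeR 0 genes passed at 10 min (37 of 3604 at unadjusted p < 0.05; DESeq2 0; limma on per-culture ratios 0) and 0 at 20 min (149 at unadjusted p < 0.05; DESeq2 1; limma 0), and 0 between the times (88; DESeq2 0). Camera at its preset correlation called 1 list lower at 10 min (iron uptake, adjusted p = 0.000585), 5 lower at 20 min, and 6 lower and 2 higher between the times, and 0 each with an estimated correlation. Over 2099 well-expressed genes the values at 10 min have an SD of 0.27 and 99% lie within 2-fold of no change, but the median SE is 0.50. Only 21.9% of the 95% intervals lie within 2-fold and 89.9% within 4-fold. These are 50.4 and 98.5% with the culture as a block (median SE 0.37), and 50.7 and 94.7% with the 20 min footprint library of replicate 2 left out of the fit (median SE 0.38). The data thus exclude changes beyond 4-fold for most genes and leave 2-fold ones open for many. None of the simulated 2-fold changes and 6.1% of the 4-fold changes in translation efficiency at 10 min were recovered. That simulation has the spread of the main fit and no pairing of mRNA and footprints by culture. It does not give the recovery of the fits with the smaller SE.

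Changes in mRNA and in footprints went together gene by gene in heat. Across 3223 genes the Pearson correlation is 0.897 at 10 min (Spearman 0.89) and 0.856 at 20 min (Spearman 0.841), where genes are not independent replicates. Splits of the cultures were compared on differences of mean log2 CPM in place of fitted changes. Over the real grouping and all other splits of the 6 cultures into 3 and 3 the values are 0.892 against at most 0.842 at 10 min and 0.87 against at most 0.8 at 20 min, though with 10 splits an exact two-sided test cannot go below 0.10.

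**Figure D2:**
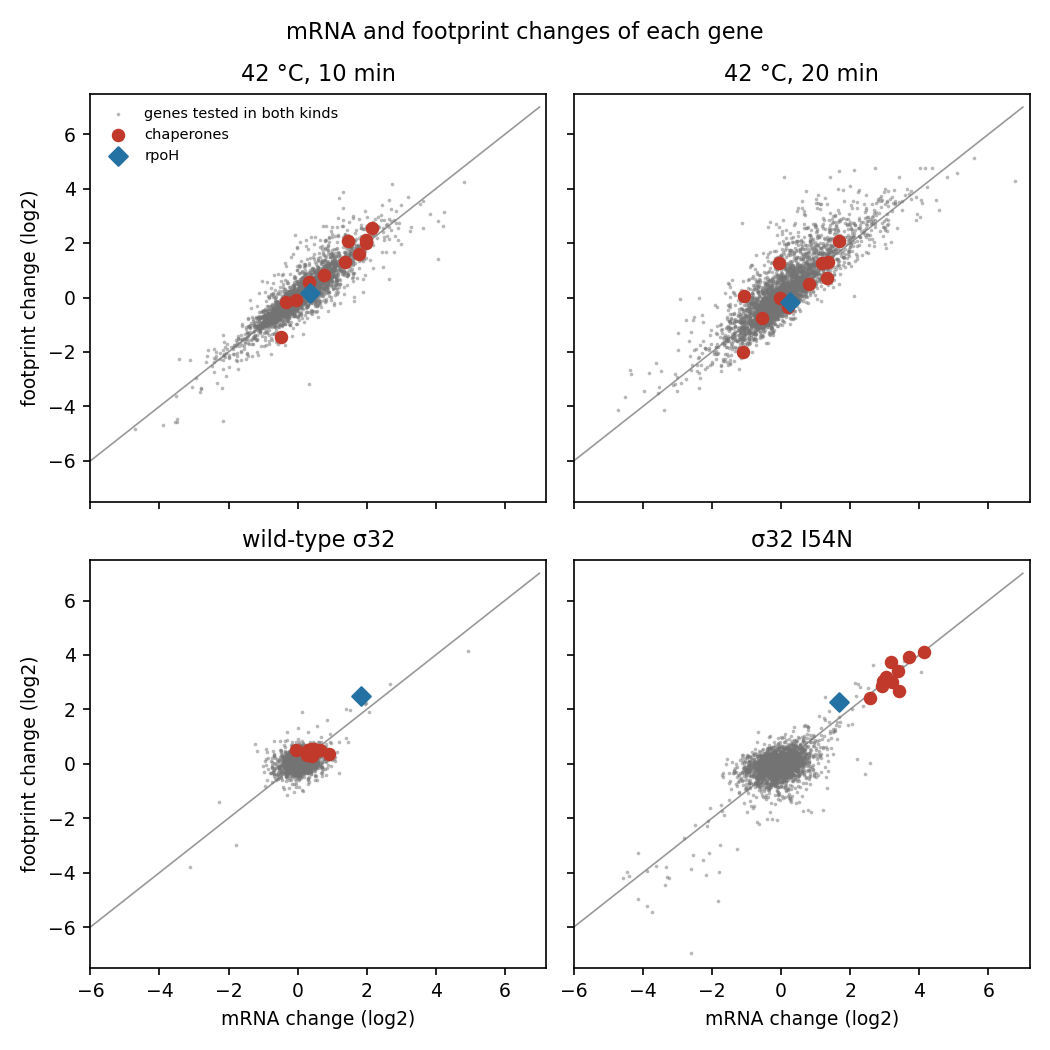
Log2 change in footprints (vertical axis) against log2 change in mRNA (horizontal axis) for genes tested in both, with the 11 chaperones as filled circles, rpoH as a diamond and the line of equal change. Pearson correlations are 0.897 and 0.856 after 10 and 20 min of heat, 0.438 with wild-type σ32 and 0.68 with σ32 I54N.

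With wild-type σ32 at 30 °C no gene passed the test in mRNA or footprints besides rpoH. Chaperone mRNAs show small values, hslR 0.91 ± 0.15, ibpA 0.64 ± 0.19, htpG 0.54 ± 0.15, grpE 0.47 ± 0.17, dnaK 0.46 ± 0.24 and groL 0.42 ± 0.23, with ibpB at −0.04 ± 0.23 (n = 3 against 4). With the replicate number as a block hslR, htpG and grpE pass (edgeR adjusted p = 0.0285, 0.0433 and 0.0405), as does the protease hslV at 0.54 ± 0.17 (0.0302). Of 11 chaperones 0 pass over all genes, 4 adjusted over the list alone and 3 with the block. Footprint values are alike, dnaJ 0.55 ± 0.17, grpE 0.55 ± 0.15, clpB 0.49 ± 0.25 and dnaK 0.47 ± 0.20, with 0 over all genes and 3 adjusted over the list alone. Counts by edgeR are 1 for mRNA (rpoH; 71 of 2810 at unadjusted p < 0.05; 6 with the block; DESeq2 2) and 1 for footprints (80 of 3043). Camera gave the chaperone list an adjusted p of 1.49e-12 for mRNA and 2.99e-12 for footprints, and 0.454 and 0.0637 with an estimated correlation, so the shift of the list stays open. Camera called 9 lists for mRNA, of which 1 holds with an estimated correlation (the 4 genes with RNA thermometers, adjusted p = 0.0136, among them rpoH itself). For footprints camera called 8, of which 2 hold (those genes and the further σ32 genes, adjusted p = 0.0108 and 0.0442).

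Translation efficiency with wild-type σ32 gave 0 genes in edgeR (56 of 3195 at unadjusted p < 0.05; DESeq2 0; limma 0) and 0 lists in camera, with rpoH itself at 0.64 ± 0.33 log2. Precision was better than in heat: over 1802 well-expressed genes the median SE is 0.27, and 80.9% of the 95% intervals lie within 2-fold (92.8% with the culture as a block). Changes in mRNA and footprints correlate at 0.438 across 2729 genes (Spearman 0.18). On differences of mean log2 CPM, which give 0.289 for the same genes and groups, 28 of 35 splits of the 7 cultures reach the value of the real one, itself included (highest other 0.655). Of the 8 that part all 3 same-numbered pairs, as the real one does, 2 do, the real one included (highest other 0.309). This correlation is thus not told from that of other groupings, and genes are not independent replicates.

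With σ32 I54N most of the heat shock regulon rose, at an rpoH level like that of the wild type. Of 11 chaperones all 11 rose in mRNA, ibpB by 4.13 ± 0.21 log2, clpB by 3.71 ± 0.28, dnaK by 3.38 ± 0.26, grpE by 3.23 ± 0.18, htpG by 3.19 ± 0.17 and groL by 3.01 ± 0.26 (n = 2 against 4). These are 3.72, 3.05, 3.00, 2.88, 3.03 and 2.53 with the library batch as a term. All 10 heat shock proteases rose, with hslV at 3.16 ± 0.18, hslU at 3.12 ± 0.16 and lon at 2.65 ± 0.16. Of 30 further σ32 genes 23 rose (27 adjusted over the list alone, where 1 also fell), with fxsA at 4.06 ± 0.24, ycjF at 3.57 ± 0.21 and ycjX at 3.51 ± 0.17. With the batch as a term the 3 counts are 11, 10 and 21. Of the 73 genes that rose in mRNA 44 are on these lists. Among the others is the glycolytic gapA, which rose by 1.16 ± 0.09 (edgeR adjusted p = 7.24e-06, and 0.000863 with the batch as a term). Footprints rose with the mRNAs of the lists, on all 11 chaperones, all 10 proteases and 20 of 30 further genes. Among them are ibpB at 4.12 ± 0.27, clpB at 3.92 ± 0.28, htpG at 3.76 ± 0.22 and dnaK at 3.42 ± 0.22. The footprint counts are 11, 6 and 12 with the batch as a term, and the last 2 are 6 and 13 without I54N replicate 2.

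Of the 30 falls with I54N only that of carB passes with the library batch as a term, and its pooled call is lost without I54N replicate 1 (−1.03). The lipid A modification genes arnA (−4.41 ± 1.02), ais (−4.14 ± 0.97) and eptA (−3.62 ± 0.83) and their regulators basR (−2.82 ± 0.59) and basS (−2.49 ± 0.56) passed pooled, but are −0.42, −0.65, −0.37, −0.75 and −0.56 with the batch as a term and do not pass. Without any 1 library but vector replicate 4 these 5 calls are lost, at −4.45 to −4.08, −4.28 to −3.82, −3.82 to −3.37, −2.88 to −2.61 and −2.56 to −2.25. Of 26 purine and pyrimidine genes 2 fell (17 adjusted over the list alone), 0 with the batch as a term, 17 without vector replicate 4 and 0 without any other library. For mRNA 103 of 2810 genes passed in edgeR (73 higher, 30 lower), 54 (53 higher, 1 lower, carB) with the batch as a term and 289 (64 higher, 225 lower) with library totals alone, where the median of all genes sits at −0.24. It is 424 (182 higher, 242 lower) without vector replicate 4, 64 without vector replicate 3, 66 without vector replicate 2, and 52 and 55 without I54N replicate 1 or 2. For footprints it is 73 of 3043 (67 higher, 6 lower), 33 with the batch as a term, 160 without vector replicate 4, 43 without I54N replicate 1 and 37 without I54N replicate 2. Camera called 7 lists for mRNA and 10 for footprints. Of these 4 hold in each with an estimated correlation: the chaperones (adjusted p = 0.00182 and 0.000177), the proteases (0.00182 and 0.00302), the further σ32 genes (0.00182 and 8.52e-05) and the RNA thermometer genes.

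Translation efficiency with I54N differed for 2 genes of the regulon. For yrfG, a nucleotide phosphatase, mRNA rose by 2.58 ± 0.15 and footprints changed by 0.02 ± 0.19, an efficiency of −2.54 ± 0.25 log2 (edgeR adjusted p = 2.88e-05, and 0.0114 with the batch as a term; n = 2 against 4). For macB, a subunit of a drug export pump, mRNA rose by 2.19 ± 0.19 and footprints changed by 0.17 ± 0.30, an efficiency of −2.0 ± 0.35 (edgeR adjusted p = 0.0433, and 1 with the batch as a term). Chaperone values lie near 0, dnaK 0.05 ± 0.37 and groL 0.03 ± 0.44, with htpG at 0.59 ± 0.29 and rpoH at 0.59 ± 0.37. The count by edgeR is 2 of 3195 (282 at unadjusted p < 0.05). It is 80 (60 higher, 20 lower) without vector replicate 4 and 1 without any other library, where macB is lost (−2.31 to −1.79), 1 with the batch as a term or library totals alone, 13 by DESeq2 and 1 by limma. Camera called 4 lists, and 0 with an estimated correlation. Changes in mRNA and footprints correlate at 0.68 across genes (Spearman 0.385; Pearson 0.532 with the batch as a term), and genes are not independent replicates. On differences of mean log2 CPM, among all 15 splits of the 6 cultures, the real one gives 0.651 and the highest other 0.605, so an exact one-sided test cannot go below 0.0667.

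Compared directly with wild-type σ32, I54N did not differ measurably in rpoH mRNA (−0.16 ± 0.21, edgeR adjusted p = 0.682) and had far more mRNA of its targets. All 11 chaperones and 10 proteases and 22 of 30 further σ32 genes (26 adjusted over the list alone, where 1 fell) were higher in mRNA, ibpB by 4.17 ± 0.23 log2, clpB by 3.42 ± 0.31, fxsA by 3.23 ± 0.25, ycjX by 3.07 ± 0.18 and dnaK by 2.93 ± 0.29 (n = 2 against 3). With the batch as a term the counts are 10, 8 and 17, and clpB is 2.42 and dnaK 2.39. In footprints 11, 8 (10 adjusted over the list alone) and 17 were higher. With the batch as a term 3 proteases and 6 further genes were, and the further genes are 11 without I54N replicate 2. The uncharacterized gene yrbL (4.10 ± 0.76) and the lipid A genes ais (−4.82 ± 0.98), arnB (−4.76 ± 1.09) and arnA (−4.75 ± 1.04) passed pooled, and with the batch as a term are 1.28, −0.90, −0.05 and −0.35 without passing. The yrbL call is lost without wild-type replicate 2 (3.89) or I54N replicate 1 (3.95). The calls of ais (−4.95 and −4.68), arnB (−4.32 and −5.52) and arnA (−4.72 and −4.79) are lost without I54N replicate 1 or 2, and those of arnB (−4.69) and arnA (−4.60) also without wild-type replicate 2. By edgeR 129 genes differ in mRNA (76 higher, 53 lower) and 42 with the batch as a term. The count is 440 (66 higher, 374 lower) with library totals alone, where the median of all genes sits at −0.29. It is 68 without wild-type replicate 2, and 49 and 54 without I54N replicate 1 or 2. For footprints it is 74 (63 higher, 11 lower), 18 with the batch as a term and 206 (46 higher, 160 lower; median −0.32) with library totals alone. It is 48 and 49 without wild-type replicate 2 or 3, and 39 and 35 without I54N replicate 1 or 2. In translation efficiency yrfG (−2.45 ± 0.26) and macB (−2.24 ± 0.38) passed (edgeR adjusted p = 9.85e-05 and 0.023). The count is 0 with the batch as a term, 1 without wild-type replicate 1 or 2 or either I54N replicate (macB lost, −2.54 to −2.02), and 45 by DESeq2. Camera called 7 lists for mRNA, 10 for footprints and 5 for translation efficiency, and 4, 4 and 0 with an estimated correlation.

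Set against each other, 10 min of heat raised the σ32 regulon less than I54N did and moved many genes that I54N left alone. The heat change minus the I54N change in mRNA is −4.94 ± 0.44 log2 for fxsA, −3.71 ± 0.22 for hslR, −3.34 ± 0.45 for ibpA, −2.45 ± 0.26 for grpE and −1.99 ± 0.39 for dnaK. It is not past the threshold for groL (−1.01 ± 0.37) or groS (−1.16 ± 0.41), but both pass without heat10 replicate 1 (−1.30 and −1.53) or vector replicate 4 (−1.22 and −1.37). Of the lists, 9 of 11 chaperones (11 adjusted over the list alone), all 10 proteases and 20 of 30 further σ32 genes (23) were lower in heat, and 6, 9 and 17 with the batch as a term. Going the other way, 14 of 28 general stress genes were higher (16 adjusted over the list alone; 10 with the batch as a term), with tktB at 3.10 ± 0.42. The ribosome-parking gene ygaM, not on that list, was higher by 4.08 ± 0.56. Of the other groups 38 of 54 ribosomal protein genes, 24 of 45 flagellar genes and 17 of 28 iron uptake genes were lower, and 7, 9 and 8 with the batch as a term or 7, 9 and 13 with library totals alone, where 1 flagellar gene was higher. Without I54N replicate 2 the ribosomal protein and flagellar counts are 23 and 13. The edgeR count is 367 of 3357 (142 higher, 225 lower), 143 with the batch as a term and 713 (620 higher, 93 lower) with library totals alone, where the median of all genes sits at 0.62. It is 238 without I54N replicate 1 and 193 without I54N replicate 2. For translation efficiency the same difference gave 0 genes in edgeR (93 of 3728 at unadjusted p < 0.05; DESeq2 1; limma 2). Camera called 18 lists for mRNA and 2 for translation efficiency, and 8 and 0 with an estimated correlation. Of the 73 genes that rose with I54N 17 rose at 10 min of heat against 6.1 expected by chance (Fisher's exact test, one-sided, p = 6.2e-05, with genes taken as units although they are not independent). Another 5 of the 73 fell, and the median heat change of all 73 is 0.10 against 1.63 with I54N. At 20 min 10 of them rose against 7.8 expected (the same Fisher's exact test, p = 0.247) and 9 fell, with a median of −0.06. In footprints 2 of the 67 that rose with I54N rose at 10 min against 0.73 expected (Fisher's exact test, p = 0.165) and 1 at 20 min against 3.3 (p = 0.968).

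Against wild-type σ32, heat gave more of several chaperones at a lower rpoH level. The heat change minus the wild-type change is 1.88 ± 0.46 log2 for clpB, 1.57 ± 0.36 for groL, 1.53 ± 0.43 for ibpB, 1.45 ± 0.33 for htpG and 1.28 ± 0.39 for groS, and −1.46 ± 0.25 for rpoH and −1.22 ± 0.21 for hslR. With the batch as a term ibpB (1.28) and groS (1.08) do not pass. The clpB call is lost without heat10 replicate 1 (1.41). The ibpB call (1.24 to 1.58) is lost without any 1 wild-type replicate, vector replicate 2 or 4, heat0 replicate 1 or 3 or heat10 replicate 2. The groS call (0.93 to 1.36) is lost without wild-type replicate 2 or 3, vector replicate 1, 2 or 4, heat0 replicate 2 or 3 or heat10 replicate 1 or 2. Heat was lower for iron uptake, fiu at −3.94 ± 0.58 and fecA at −3.10 ± 0.81, and higher for talA (transaldolase) at 3.38 ± 0.51 and poxB at 3.18 ± 0.50. The fecA call is lost without wild-type replicate 3 (−2.93), heat10 replicate 1 (−2.84) or heat0 replicate 2 (−2.31). The edgeR count is 324 of 3357 (151 higher, 173 lower), 246 with the batch as a term and 381 (305 higher, 76 lower; median 0.31) with library totals alone, and 198 without heat0 replicate 3. Camera called 12 lists, and 4 with an estimated correlation.

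The share of reads spent on chaperones compares the conditions directly. In the mRNA libraries the 11 chaperone genes took 1.00 ± 0.19% of coding reads at 30 °C (mean ± SD), 4.04 ± 1.08% after 10 min and 2.67 ± 0.60% after 20 min of heat (n = 3 each). In the plasmid experiment they took 0.89 ± 0.20% with vector (n = 4), 1.25 ± 0.28% with wild-type σ32 (n = 3) and 6.94 ± 0.08% with I54N (n = 2). In footprints the shares are 1.30 ± 0.32, 4.96 ± 1.91 and 3.15 ± 0.78%, and 1.17 ± 0.30, 1.61 ± 0.38 and 9.46 ± 0.46%. Ribosomal protein genes went from 28.3 ± 0.50 to 21.0 ± 0.98 and 22.0 ± 2.87% of mRNA coding reads in heat. Heat and I54N groups do not overlap with their controls in chaperone share, where an exact two-sided permutation test cannot go below 0.10 and 0.0667, while wild type and vector overlap (exact two-sided p = 0.143 for mRNA and 0.171 for footprints). Within the 3 same-numbered pairs of vector and wild type the share rose each time, by 0.21 to 0.57 percentage points in mRNA and by 0.36 to 0.67 in footprints, where an exact paired test cannot go below 0.25.

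**Figure D3:**
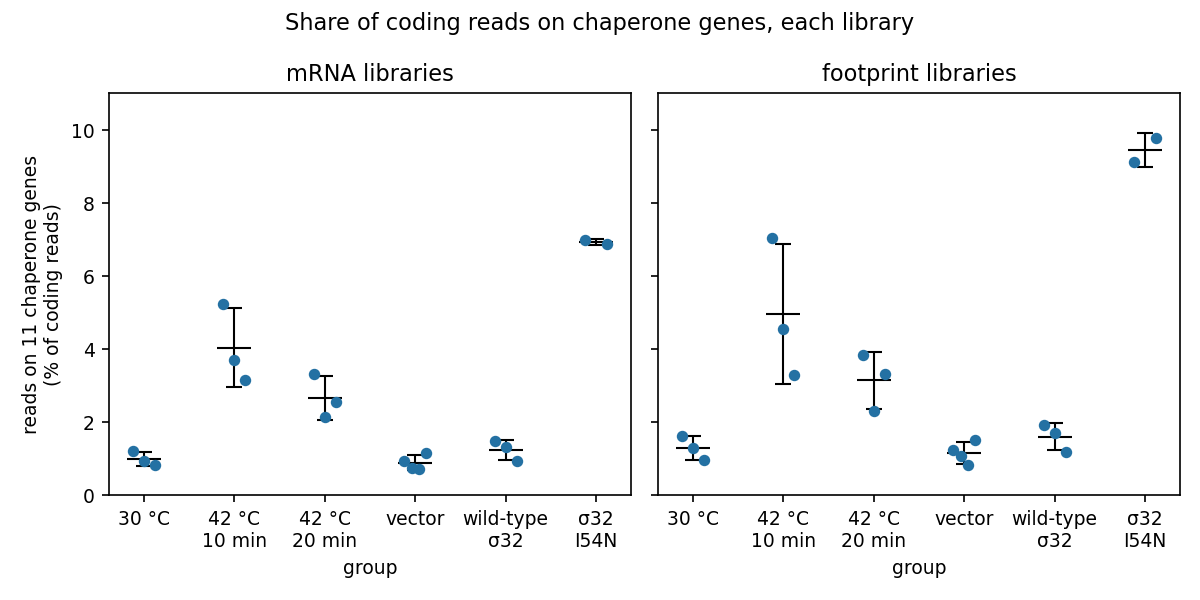
Percent of coding reads on 11 chaperone genes (vertical axis) in each mRNA library (left) and footprint library (right) by group, with points for libraries and bars for mean ± SD. I54N stands highest at 6.94% of mRNA reads and 9.46% of footprint reads, against 0.89% and 1.17% with vector.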

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

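In this part the test of a mislabelled library, the tests on genes higher or lower with I54N, the weak genes tested in both experiments and the splits that part all pairs were chosen only after the result was seen.

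The first pattern is the 20 min footprint library of replicate 2, which departs from replicates 1 and 3 with an SD of 1.47 log2 across 3341 genes. Its departure follows the difference between mRNA and footprints of the other 2 cultures (r = 0.827, slope 1.12; the same r is 0.155 and 0.103 for the others), which is what mRNA fragments counted as footprints would give. Its mean correlation with the mRNA of the other 2 cultures is above that with their footprints by 0.115 (0.917 against 0.802), so an mRNA library under a footprint label is also possible, and these 2 explanations stay open. Low depth is excluded, since with all footprint libraries thinned to 1063068 reads its mean correlation with its group is 0.805 and the lowest other is 0.929. If either holds, part of the 20 min footprint and translation efficiency change is the difference between the 2 kinds of library. Without it the correlation of mRNA and footprint changes goes from 0.856 to 0.917, the SD of translation efficiency from 0.491 to 0.414 and the footprint count from 343 to 754.

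The second pattern is that weakly expressed genes gain at 42 °C relative to strong ones. Genes under 10 CPM with vector have a median change of 0.68 at 10 min and genes of at least 100 CPM −0.34, a difference of 1.02 for mRNA and 1.18 for footprints (1.18 and 1.82 at 20 min), against 0.19 with wild-type σ32 and 0.34 with I54N for mRNA. Each experiment tests its own genes. On the 237 weak genes tested for mRNA in both, the differences are 0.76 at 10 min, 0.91 at 20 min, 0.19 and 0.35, and on the 488 tested for footprints in both they are 0.93, 1.38, −0.02 and 0.01. Unequal depth is excluded, since after thinning to 774961 reads the difference is 0.95. An even background of reads, as from DNA, does not lead the gain, which does not grow with gene length (rho 0.036). A smaller background stays open, since weak genes were chosen by CPM without regard to length and the largest gains can hide it. Release of genes silenced by H-NS or lying in prophages is not seen as the main source at 10 min. The median of the 49 genes tested, of 102 listed, lies at percentile 59 of matched random lists, which may hold unlisted targets. At 20 min it lies at percentile 93.2, which leaves this undecided. The cause stays unknown; a falling total of the strong mRNAs, such as those of ribosomal proteins, would lift all others in relative terms and was not tested.

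The third pattern is the part of the I54N result that goes with the library batch, which is inferred from the transfer RNA share of mRNA libraries and not named in the labels. The 30 genes lower with I54N have a median change of −1.14, of −0.53 with the batch as a term, and 29 of them are also lower in vector replicate 4, with a median of −0.66, the only vector culture of that batch. Much of these falls, arnA and basR among them, is thus shared with vector replicate 4. Library preparation and the state of the cultures cannot be told apart as its source with 1 such vector culture. For the 73 genes higher with I54N (median 1.63) the batch is excluded as the sole cause, since the median is 1.41 with the batch as a term, though vector replicate 4 is above the other vectors by 0.33 for them. A larger share of reads on the 10 most abundant genes can only lower the others, so it could not have given rises in them. That share, over the top 10 of each library, goes from 17.05 to 17.75% with vector to 19.12 and 19.2% with I54N. This moves every other gene by −0.03, and risen genes may themselves be among the 10. The batch estimate rests on vector replicate 4 alone.

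Among 86 groups of 4 libraries tested for a value far from the others, 7 were found, and chance flags about 1 in 20 groups. Of the vector mRNA libraries, replicate 4 has 50.516% ribosomal and 34.914% transfer RNA, and single libraries stand off with 0.874% of coding reads on cold shock genes, 1.369% on glycolysis and 0.112% on RNA thermometer genes. Of the vector footprint libraries single ones stand off with 21.81% of coding reads on the 10 most abundant genes and 0.021% on arabinose genes. By tests of the difference itself, heat at 10 min differed from I54N for 367 mRNAs and from wild-type σ32 for 324.

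Small RNAs and other entries left out of the main counts also changed in mRNA libraries by edgeR's quasi-likelihood test. After 10 min ryjA rose by 2.90, sdsR (an RpoS-dependent small RNA) by 2.21, rybB by 1.55, fdhF by 1.36 and tpke11 by 1.11, and ryhB, the small RNA of iron shortage, fell by 3.04. After 20 min ryjA rose by 3.80, sdsR by 3.45, sibC by 2.07, fdnG by 1.88, fdhF by 1.60 and tpke11 by 0.65, and ryhB changed by −3.83. With I54N tpke11, next to dnaK, rose by 3.76 and the insertion sequence copies insL-1, insL-2 and insL-3 by 1.61, 1.72 and 1.64. The copies have near-equal average log2 CPM (3.64, 3.63 and 3.66). The counts are estimates that may split shared reads among copies, so these may be 1 signal. The libraries hold fragments of 20 to 40 nt, and small RNAs are caught unevenly.

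Other splits of the libraries were counted with the same test. For 3 against 3 the 10 splits are too few to exclude chance. The real split ranks alone at 10 and at 20 min for mRNA and for footprints (1 of 10 splits with as many genes, highest other 0), and for translation efficiency at both times and between the times all 10 tie at 0. Between 20 and 10 min 2 splits reach the mRNA count (highest other 56), and for footprints all 10 do (highest other 268). Both highest counts come from 1 split, which holds the cultures of replicate 1 together and those of replicate 2 together. It sets heat10 replicate 1 and heat20 replicates 1 and 3 against the rest, and what sets them apart was not tested. For wild-type σ32 5 of 35 splits reach the mRNA count (highest other 17), 4 the footprint count (63), and all 35 the translation efficiency count (1). The larger counts come from splits that hold same-numbered cultures together. Of the 8 that part all 3 pairs only the real one calls a gene in mRNA or in footprints, and 8 are too few to exclude chance. For heat minus wild-type σ32 10 of 100 pairs of splits reach 324 (highest other 463). All 10 are among 13 that keep the cultures at 30 °C and 42 °C apart and regroup the plasmid cultures alone, so they carry the heat change and do not decide. The other 87 give at most 4 genes.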

How the results depend on the processing

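The limits of these results are few replicates, a library batch inferred from the transfer RNA share for both I54N cultures and vector replicate 4, one odd footprint library at 20 min, and scaling that shows relative amounts only. Tests with the batch as a term, with all entries of the raw table, with the 20 min library left out of the fit, with each library left out of heat minus σ32, with shares taken within same-numbered pairs and with the authors' values for translation efficiency were chosen only after the result was seen. Except where stated the cause was not tested. Where a group is left with 1 culture, it is assumed to vary like the others.

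With library totals alone the counts of genes are 1015 (heat 10 min, mRNA), 1 (20 against 10 min, mRNA), 2 (wild-type σ32, mRNA), 289, 440 and 713 (I54N, I54N against wild type and heat 10 min minus I54N, mRNA), 206 (I54N against wild type, footprints) and 1 (I54N, translation efficiency), by construction through a shifted median. With RLE size factors the count is 1 for 20 against 10 min mRNA. With no filter on low counts it is 1 for 20 against 10 min mRNA and 2 for wild-type σ32 mRNA, and with a mean count of at least 64 it is 1, 2 and, for heat 20 min mRNA, 578, with fewer genes tested. DESeq2 gives 30 and 7 (20 against 10 min, mRNA and footprints), 226 and 597 (heat 10 and 20 min, footprints), 1 (heat 20 min, translation efficiency), 2 (wild-type σ32, mRNA), 190, 120 and 13 (I54N mRNA, footprints, translation efficiency), 282, 148 and 45 (I54N against wild type, in that order) and 1 (heat 10 min minus I54N, translation efficiency).

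With the replicate block the counts are 1485, 1821 and 223 (mRNA at 10 min, 20 min and between), 289, 737 and 2 (footprints in that order), 6 (wild-type σ32, mRNA), 528 and 426 (I54N, mRNA and footprints), 580, 361 and 23 (I54N against wild type, mRNA, footprints and translation efficiency) and 1 (heat 10 min minus I54N, translation efficiency). The translation efficiency counts come from a block on the culture instead. For the mRNA and footprint counts, the numbers do not pair for I54N or for footprints at 20 min. Besides the calls given with the results the block changed no other count by more than 1.5 times. With only the groups compared in the fit the counts are 0 (20 against 10 min, mRNA), 288 and 173 (heat 10 and 20 min, footprints), 293 and 18 (I54N against wild type, mRNA and translation efficiency) and, with only the 4 groups of the contrast, 1 (heat 10 min minus I54N, translation efficiency).

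The authors' normalized values with limma give 98 (heat 10 min, footprints), 1, 1 and 2 (translation efficiency of I54N, I54N against wild type and heat 10 min minus I54N). With pseudocount 0.1 they give 0 (20 against 10 min, mRNA) and 85 (I54N against wild type, mRNA), and with all genes above 0 they give 0, 66 and, for I54N mRNA, 68. Limma on per-culture ratios gives 1, 1 and 2 for the same 3 translation efficiency contrasts. With the library batch as a term the counts are 54, 33 and 1 (I54N mRNA, footprints, translation efficiency), 42, 18 and 0 (I54N against wild type, in that order) and 143 (heat 10 min minus I54N, mRNA). There the 30 mRNA falls with I54N go from a median of −1.14 to −0.53 at a median SE of 0.24 and 0.23, and the 73 rises from 1.63 to 1.41 at 0.18 and 0.25. All entries of the raw table give 1 (20 against 10 min, mRNA), 27 (heat 10 min, footprints), 81 (I54N against wild type, mRNA) and 1 and 1 (translation efficiency of I54N and of I54N against wild type). With the 20 min replicate 2 left out of the fit, heat 10 min footprints give 307.

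Leaving out each library in turn, the counts range from 345 to 627 (heat 10 min, mRNA), 548 to 1187 (20 min, mRNA), 0 to 0 (between, mRNA), 0 to 1 (10 min, footprints), 5 to 754 (20 min, footprints), 0 to 1 (wild-type σ32, footprints), 52 to 424, 37 to 160 and 1 to 80 (I54N mRNA, footprints, translation efficiency) and 49 to 189, 35 to 59 and 1 to 2 (I54N against wild type, in that order). For heat 10 min minus σ32 they range from 193 to 427 (I54N, mRNA), 198 to 355 (wild type, mRNA) and 0 to 0 (I54N, translation efficiency). Correlations of mRNA with footprint changes range from 0.827 to 0.89 (10 min), 0.765 to 0.917 (20 min), 0.315 to 0.603 (wild type) and 0.578 to 0.707 (I54N). With no filter they are 0.655, 0.662, 0.077 and 0.291, and with a mean count of at least 64 they are 0.949 at 10 min, 0.875 at 20 min (Spearman 0.795 against 0.841), 0.607 with wild type and 0.812 with I54N. Spearman rho is 0.18 with wild type and 0.385 with I54N, where Pearson r with the batch as a term is 0.532.

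With an estimated correlation camera calls 2 and 1 lists at 10 min (mRNA, footprints), 2 and 1 at 20 min, 1 and 2 with wild type and 4 and 4 with I54N, against 15 and 15, 15 and 16, 9 and 8, and 7 and 10. Between the times it calls 0 and 0 against 15 and 14, for I54N against wild type 4 and 4 against 7 and 10, and for heat 10 min minus I54N and minus wild type (mRNA) 8 and 4 against 18 and 12. For translation efficiency it calls 0 in each contrast, against 1, 5 and 8 (10 min, 20 min, between), 0 (wild type), 4 (I54N), 5 (I54N against wild type) and 2 (heat 10 min minus I54N). Without the 10 most abundant genes in the total, the gain in chaperone share in mRNA is 1.82 percentage points at 10 min, 0.97 at 20 min and 4.88 with I54N, and in footprints 0.99 at 20 min and 6.88 with I54N, by construction, since groL is one of the 10 and leaves the list with them. Over 185 named gene values and 3256 repeats, 2839 kept call and direction, 322 lost the call, 49 gained it, 46 without a call changed sign and 0 reversed.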

Other observations

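Several groups of genes not described so far changed in heat. Of 13 methionine genes 6 fell in mRNA at 10 min (7 adjusted over the list alone) and 8 at 20 min, with metF at −2.16 ± 0.46 log2 and −2.21 ± 0.45 (n = 3 against 3). The count at 10 min is 9 with the replicate number as a block, 3 with library totals alone and 3 without heat0 replicate 3. Of 18 genes of the oxidative stress response 6 rose and 1 fell at 10 min, with catalase katG at 1.61 ± 0.45 and marB at 1.59 ± 0.32 up and the manganese superoxide dismutase sodA at −1.38 ± 0.21. These are 11 and 2 with the block, 11 and 1 with library totals alone, and 3 rises without heat0 replicate 2, heat0 replicate 3 or heat10 replicate 2. The katG call (1.29 to 1.74) is lost without any 1 library but heat0 replicate 1, without which 2 genes fell. sodA went to −2.35 ± 0.22 at 20 min. Of 13 glycolytic genes 2 rose at 10 min, the isoenzyme genes fbaB (2.20 ± 0.24) and pfkB (2.14 ± 0.44), against 5 with the block, where 2 also fell, and 6 with library totals alone. The envelope protease degP rose by 1.53 ± 0.16.

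Of 20 toxin and antitoxin genes 0 passed at 10 min over all genes (4 with the block, 7 with library totals alone) and 6 rose at 20 min (7 adjusted over the list alone; 10 with the block), among them chpS at 1.46 ± 0.46, but 0 without heat20 replicate 1, 1 without heat0 replicate 2 or 3 and 2 without heat20 replicate 3, with chpS (1.10 to 1.50) lost in each. Of 6 arabinose genes 2 rose at 20 min without arabinose, the regulator araC by 2.09 ± 0.45 and the transporter gene araH by 1.48 ± 0.44 (4 with the block), and 1 did without heat20 replicate 1 or 3 or heat0 replicate 2 or 3, where araH (1.09 to 1.54) is lost. Of these 8 risen genes 3 lie under 10 CPM with vector, among them chpS and araH at 5.0 and 4.6 CPM, and belong to the weak genes that gain at 42 °C. The others lie above that limit, 4 toxin and antitoxin genes at 11.5 to 32.2 CPM and araC at 173.6 CPM, where arabinose and a pBAD plasmid are present.

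In this part the neighbour tests were chosen only after the result was seen. The genes yrfG and macB gained mRNA with I54N and no footprints, and yrfG lies next to hslR. A candidate explanation is transcription that runs from a σ32 promoter through a neighbour whose mRNA is not translated. Over 45 neighbours of the 44 risen σ32 genes, taken on either side and outside the σ32 lists, the median translation efficiency lies at percentile 23.8 of matched random sets (33.7 with the batch as a term). Only 5 of the 45 rose in mRNA and their median mRNA change is −0.06, so this value decides nothing and read-through stays open. Of the 5, menA shows mRNA at 1.50, footprints at 0.37 and translation efficiency at −1.12 ± 0.28 (edgeR adjusted p = 0.21), and rsmJ 2.06, 2.02 and −0.02. Other neighbours with positive mRNA values go both ways. With mRNA at 1.95, 0.92 and 0.75, yhdN, lnt and folP have translation efficiencies of −0.50 ± 0.46, 0.15 ± 0.26 and 0.66 ± 0.24. Reads and start sites would decide it.

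The heat response here is much wider than the σ32 regulon. At 10 min 17 of the 73 mRNAs raised by I54N rose, and 13 of the 30 lowered by I54N fell against 3.5 by chance (Fisher's exact test, one-sided, p = 1.22e-05, with genes as units although they are not independent). At 20 min 10 of the 73 rose against 7.8 expected (Fisher's exact test, p = 0.247) and 14 of the 30 fell against 4.8 (p = 7.69e-05). In footprints a single gene of 6 fell at each time, against 0.048 expected at 10 min (Fisher's exact test, p = 0.0468) and 0.21 at 20 min (p = 0.191). What the overlap of the falls means stays open, since those 30 genes are also lower in vector replicate 4 (−0.66). No heat library shares the high transfer RNA of that inferred batch. The small TMM-scaled rise of rpoH mRNA in heat and its translation efficiency (−0.12 ± 0.34, not told from no change) do not address σ32 protein, which these libraries do not measure. A later time course of footprints with cultures paired throughout, and I54N with controls in the same library batch, would settle the comparisons left open.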
